A study of Mus musculus with 2 samples.

How the data were processed

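Skeletal muscle RNA of wild-type and Jhdm2a null mice was measured on 2 Affymetrix Mouse Genome 430 2 arrays, 1 per genotype, each with RNA combined from 3 mice before labelling. The values are MAS5 signal intensity per probe set on a linear scale, as deposited by the authors. MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. Both arrays had a 2% trimmed mean of 500 in the deposited table, so they had been scaled to a common level before deposit. The table used here carries no detection calls, which is why a floor on the signal was used in their place. Groups were taken from the source label of each sample. 0 columns of other samples were present.

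Both arrays were set to the same 2% trimmed mean, which left the values unchanged. The 64 control probe sets were left out of the gene values. A floor was set at the 60th percentile of all non-control probe sets of both arrays, a signal of 182. A probe set was measured when above the floor on both arrays, and a gene's value was the mean log2 ratio of its measured probe sets, null-labelled over wild-type-labelled. A gene was counted when that mean reached 2-fold and all its measured probe sets had the same sign. This sign rule left out 1 gene past 2-fold, Idh3b. Genes with no probe set above the floor on 1 array and at least 1 probe set at 2 times the floor or more on the other were given a bound, the brighter signal over the floor, written as at least N-fold.

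Of 45037 non-control probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed here. Only probe sets with 1 symbol entered the gene values. Of the named probe sets, 34754 matched a gene identifier in a table of RefSeq genes on the assembly GRCm38.p6, and 0 symbols had to be renamed. That table served only for names and for which genes neighbour each other, because the files name no genome build.

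Before the data were examined, 44 gene lists for muscle metabolism, contraction, stress programmes and other cell types were fixed, along with the counting rule and the alternatives. For the 41 lists with 5 or more measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 10 bins. A list was called outside the range when its median lay outside the central 95%. These percentiles describe the 2 arrays and are not tests. Members at least 1.5-fold higher or lower were counted.

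The genes named are Kdm3a, Kdm3b and Jmjd1c; the 10 highest and 10 lowest measured genes whose probe sets have 1 sign and whose brighter array reads at least 2 times the floor; and the 4 largest bounds in each direction. Added to these are up to 4 members of each list with the largest absolute log2 ratio, 3 genes within 20 Mb of Kdm3a, and a fixed set of muscle, fat, blood and clock genes such as Ppara, Acadm, Pdk4, Ucp3, Ppargc1a and Myh4. From that set Cpt1b, Ucp2, Cfd, Ddx3y and Hbb-b1 had no probe set with 1 symbol here, and Hba-a1 and Xist were not above the floor on both arrays. In the results Cd36, Lpl, Fabp3, Mlycd and Scd1 stand outside this rule and were named after their values were seen, as were the isoform pairs, muscle and liver genes of the closing observations.

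A further 6 lists were written after the 40 highest and lowest genes had been seen. They hold 35 brown adipocyte genes, 34 hepatocyte genes, 29 neutrophil genes, 17 muscle forms of metabolic enzymes, 15 bone genes and 4 PPAR-responsive genes of muscle fibres. In these lists a gene above the floor on either array was used, with signals under the floor set to the floor and the mean taken over its probe sets above the floor on either array. Medians over measured genes of these lists use the gene values above.

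With 1 pooled array per genotype no test between genotypes has residual degrees of freedom, so none was run. The error given is technical: the SD between probe sets of a gene and the ratios of 18 hybridisation control probe sets. The 3' over 5' signal ratio of the Gapdh controls was 0.813 on the wild-type-labelled and 0.828 on the null-labelled array, and that of the beta-actin controls 0.999 and 0.864.

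The procedure was tested on simulated data for this comparison, over 9910 genes with a noise SD of 0.318. It counted 98.8% of 80 genes raised 3-fold and 62.5% of 80 genes lowered 3-fold, since only 50 of the lowered genes stayed above the floor, and 100% of those were counted. Of 40 genes raised 1.5-fold, 7.5% were counted at 2-fold, and 4 unchanged genes were counted as higher and 7 as lower. The noise had the same SD at every signal and was drawn separately for each probe set, so false counts on real arrays may be higher. A list of 30 genes lowered by 0.5 fell at percentile 0, and 7 of 100 unchanged lists of 20 genes lay outside the central 95%.

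Alternatives were the values as deposited, quantile normalization, the median log2 ratio set to 0, loess of log2 ratio on mean log2 signal with a span of 0.3, floors at the 50th and 75th percentiles, the brightest probe set per gene, leaving out probe sets whose names mark possible cross-hybridisation (_x_at and _s_at), no sign rule, a 1.5-fold threshold, random lists not matched on signal, and windows of 10 and 40 Mb around Kdm3a. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.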

Results

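Total RNA from mouse skeletal muscle was measured on 2 Affymetrix Mouse Genome 430 2 arrays, 1 for wild-type animals and 1 for animals null for Jhdm2a. Jhdm2a, named Kdm3a in current annotation, is a Jumonji-domain enzyme that removes mono- and dimethyl marks from lysine 9 of histone H3. Each array carried RNA pooled from 3 male mice aged 3 months. The strain label names 129 embryonic stem cells and a backcross of 4 generations onto C57BL/6. The comparison asks which muscle transcripts differ in level when the demethylase is disrupted. With 1 array per genotype the difference has no replicate check. No p-value was computed, and a level is called higher or lower only as a description of these 2 arrays, whose number limits the precision. The median MAS5 signal was 112 on each array, and 18004 probe sets on the wild-type array and 18026 on the null array lay above the signal floor of 182.

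The Kdm3a transcript was not lower in the RNA labelled null. Its 1 probe set, 1426810_at, read 406 on the wild-type-labelled array and 488 on the null-labelled array, 1.20-fold higher (log2 ratio 0.26). Where this probe set lies relative to the disrupted part of the gene is not given in the sources used here, and a probe set outside that part checks nothing about the labels. The arrays are therefore called wild-type-labelled and null-labelled throughout, and every direction below rests on those labels. The paralogs Kdm3b and Jmjd1c, which encode related demethylases, had log2 ratios of 0.06 and 0.30, each from the 1 probe set above the floor on both arrays. None of the 20 other histone lysine demethylases measured, and none of the 7 enzymes and readers of H3K9 methylation, differed by 1.5-fold. Their list medians were -0.01 and -0.05.

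Most transcripts had closely similar signals in both pools, and those that differed strongly were mainly lower on the null-labelled array. Among 9696 measured genes, 36 were at least 2-fold higher and 229 at least 2-fold lower, so 86.4% of the counted genes were lower. At 4-fold the counts were 2 higher and 69 lower, and 32 genes were lower by 8-fold or more against 0 higher. Another 101 genes had no probe set above the floor on 1 array and read at least 2 times the floor on the other, 11 of them on the null-labelled and 90 on the wild-type-labelled array. The median log2 ratio of all measured genes was 0.04 with an SD of 0.46, and 97.3% of genes lay within 2-fold. Across genes, which are not independent replicates, the log2 signals correlated with r = 0.951. Probe sets of the same gene gave log2 ratios that differed with an SD of 0.27 per probe set over 3719 genes, and 18 hybridisation controls had a mean log2 ratio of -0.02 ± 0.09 (SD). Both figures are technical and cover no variation between mice. Raising the floor to the 75th percentile of signals left 11 genes higher and 113 lower, because the dimmer genes then went unmeasured.

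The 10 lowest measured genes came from several groups, and 6 of them stand in the adipocyte, lipogenesis or thermogenic lists. Ucp1, the uncoupling protein through which brown fat makes heat, had a signal of 14885 on the wild-type-labelled and 283 on the null-labelled array, 52.5-fold lower. Cidea, a lipid droplet protein abundant in brown fat, was 37.0-fold lower, and its relative Cidec 16.2-fold lower. Pygl, the liver form of glycogen phosphorylase, was 28.1-fold lower, and Pck1, the cytosolic enzyme that makes phosphoenolpyruvate from oxaloacetate, was 23.3-fold lower. Elovl6, which elongates fatty acids, and Agpat2, which acylates lysophosphatidic acid in triglyceride synthesis, were 21.7-fold and 19.3-fold lower. Apoc1, an apolipoprotein, was 20.5-fold lower. Prkar2b, a regulatory subunit of protein kinase A, had a log2 ratio of -4.78 ± 0.41 (SD of 2 probe sets). Tkt, the transketolase of the pentose phosphate pathway, had -4.12 ± 1.08 (SD of 2 probe sets).

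**Figure D1:**
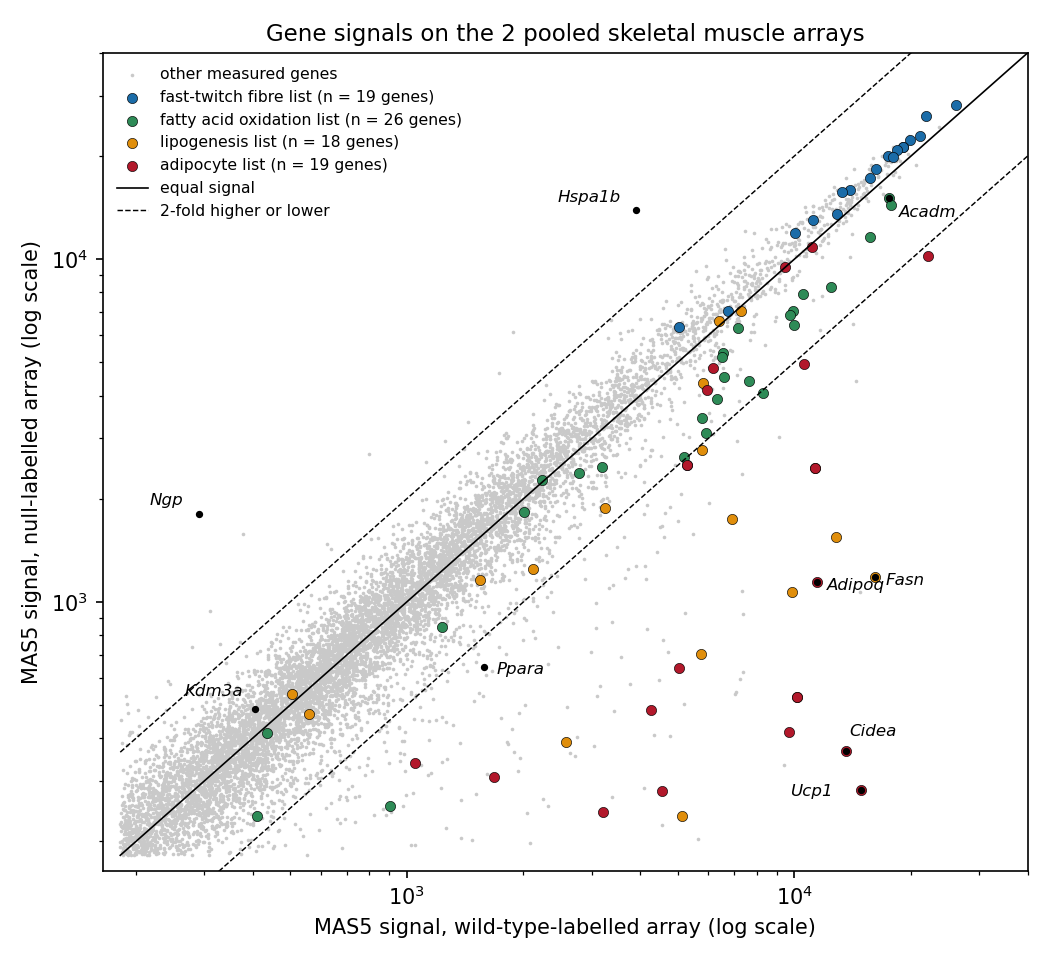
MAS5 signal of each measured gene on the wild-type-labelled array (x axis, log scale) against the null-labelled array (y axis, log scale); each point is 1 gene, coloured points are members of 4 gene lists (a gene in more than 1 list carries the colour drawn last), the solid line marks equal signal and the dashed lines 2-fold. Ucp1 lies farthest below the line at 52.5-fold lower, and most fast-twitch fibre genes lie along it.

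The 19 measured adipocyte markers, 11 of which another fixed list holds too, were all lower on the null-labelled array, with a median log2 ratio of -2.98 (7.89-fold), below each of 10000 random lists matched on signal. Of these, 16 were at least 1.5-fold lower. Adipoq, the hormone adiponectin, was 9.99-fold lower, while Cd36 and Lpl, which muscle also makes to take up fatty acids, had log2 ratios of -0.31 and -0.12. In the list of fatty acid synthesis and esterification, 12 of 18 genes were at least 1.5-fold lower and the median was -1.51, again below every random list. Fasn, the fatty acid synthase, was 13.6-fold lower, and Agpat2 and Scd1 also stand in the adipocyte list. Acly, which supplies cytosolic acetyl-CoA, had -3.23 ± 0.06 (SD of 3 probe sets). Sterol synthesis genes were lower by less, with a median of -0.41 over 14 genes at the 0.01 percentile. All 14 of them were below 0, and Insig1, a sterol sensor of the endoplasmic reticulum, was the lowest at -2.37. The lipogenesis and sterol medians were not separated from hepatocyte genes, of which 21 of 21 were lower in a list added after values were seen. The list of uncoupling and thermogenic genes had a median of -0.16 over 10 genes at percentile 1.87, with Ucp1 and Cidea low and Ucp3, the uncoupling protein of muscle, at 0.46. With the floor at the 75th percentile this median was 0.20 and within the range of random lists. The adipocyte and lipogenesis medians were then -1.10 and -0.92.

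Genes of fatty acid oxidation were lower on the null-labelled array by a modest amount. The median log2 ratio of 26 genes was -0.50 (1.41-fold lower), the mean -0.53 ± 0.38 (SD over genes), and 25 of the 26 were below 0, with 8 at least 1.5-fold lower. No random list had so low a median. Ehhadh, the bifunctional enzyme of peroxisomal oxidation, was lowest at -1.83. The short-chain dehydrogenase Acads, the thiolase Acaa2 and the carnitine palmitoyltransferase Cpt2 had -0.97, -0.95 and -0.93. The acyl-CoA dehydrogenases for very long, long and medium chains, Acadvl, Acadl and Acadm, had -0.58, -0.43 and -0.22, and Mlycd, a malonyl-CoA decarboxylase, was the 1 member above 0 at 0.02. Brown fat and liver genes differed in the same direction, with Ucp1 52.5-fold lower, the adipocyte list at a median of -2.98, and all 21 genes of a hepatocyte list lower, 16 of them at least 2-fold. The hepatocyte list was added after values were seen. Liver also expresses genes of fatty acid oxidation.

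Ppara, the nuclear receptor that drives fatty acid oxidation genes, was lower in each of its 3 probe sets, with log2 ratios of -1.46, -1.21 and -1.15 and a mean of -1.27 (2.41-fold lower). Its brightest probe set read 2220 on the wild-type-labelled and 809 on the null-labelled array. The list of metabolic nuclear receptors and coactivators lay within the range of random lists, with a median of -0.01 over 24 genes at percentile 17.5. Of its members 3 were at least 1.5-fold lower, Ppara, the liver X receptor Nr1h3 at -0.97 and the coactivator Ppargc1b at -0.82. Ppargc1a, the coactivator that promotes mitochondrial biogenesis, had 0.16, and Nr3c1, the glucocorticoid receptor, 0.57. Among 20 known PPAR target genes the median was -0.26 at percentile 0, and 5 genes were at least 1.5-fold lower against 0 higher. Plin2 and Plin5, which coat lipid droplets, had -2.76 and -1.24, the lipoprotein lipase inhibitor Angptl4 had -2.49, and the glycerol channel Aqp7 had -2.45. Pdk4, a kinase that spares glucose by inhibiting pyruvate dehydrogenase, had -0.11, and the fatty acid binding protein Fabp3 had 0.25. Of these targets, 7 also stand in the fatty acid oxidation list. On the same array Ucp1 was 52.5-fold lower, and 21 of 21 hepatocyte genes above the floor on either array were lower.

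Respiratory chain genes had medians near that of all genes. Over 33 subunits of complex I the median log2 ratio was 0.06 at percentile 9.07, though -0.0100 after quantile normalization and -0.0384 after loess, and 0 genes differed by 1.5-fold. Over 40 subunits of complexes II to V the median was 0.05 at percentile 2.57, just within the range of random lists. It was -0.0330 after quantile normalization and -0.0632 after loess, and lay below the range in 5 of 8 alternatives. Its 2 genes past 1.5-fold were the cytochrome oxidase subunits Cox6a1 at -2.04 ± 1.23 (SD of 2 probe sets) and Cox8a at -1.64 ± 0.09 (SD of 2 probe sets). Tricarboxylic acid cycle genes had a median of -0.01 over 22 genes at percentile 1.96, where Pcx, the pyruvate carboxylase, had -1.69 and Idh3b, an isocitrate dehydrogenase subunit, had -1.23 with probe sets of opposite sign. Without those 2 genes the median was 0.01 at percentile 3.46, inside the range. Glycolysis, glycogen metabolism and insulin signalling lists had medians of 0.04, 0.16 and 0.06, all within range. In glycolysis the liver form of phosphofructokinase, Pfkl, had -3.31 and the phosphoglycerate mutase Pgam1 -2.50. The insulin-sensitive glucose transporter Slc2a4 had 0.24, but -0.04 from its brightest probe set, and the transporter Slc2a3 had 0.84.

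Fibre-type lists had medians within the range of random lists, with single members that differed. The fast-twitch list had a median of 0.17 over 19 genes at percentile 78.1, with the fast myosin heavy chains Myh1, Myh2 and Myh4 at 0.15, 0.18 and 0.19. After loess that median was 0.0546. The slow-twitch list had a median of -0.02 over 16 genes at percentile 7.62, with the slow myosin heavy chain Myh7 at -0.09. That median was -0.11 after loess and 0.09 from the brightest probe set of each gene. In the slow list 2 genes were at least 1.5-fold higher, the Z-disc proteins Myoz2 at 0.70 and Csrp3 at 0.65, and 1 lower, the carbonic anhydrase Car3 at -0.67 ± 0.82 (SD of 4 probe sets that disagree in sign). In the fast list Gpd1, a glycerol phosphate dehydrogenase, was lower at -0.77 ± 0.47 (SD of 3 probe sets), and Myoz1 had 0.57 ± 0.56 (SD of 2 probe sets). Car3 and Gpd1 also stand in the adipocyte list. Sarcomere genes shared by fibre types had a median of 0.23 over 24 genes at percentile 98.3, above the range here and in 5 of 8 alternatives, with the small heat shock protein Hspb7 at 0.88 and the myosin binding protein Mybpc1 at 0.68. Genes of excitation and calcium handling had a median of 0.16 over 18 genes, and the sodium pump subunit Atp1b1 had 1.05. Lists of satellite cell and myogenic factors, denervation genes, atrophy genes, proteasome subunits, cytosolic ribosomal proteins and mitochondrial ribosomal proteins lay within range, with medians of 0.10, 0.08, 0.00, 0.15, 0.12 and 0.08.

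Genes higher on the null-labelled array included some neutrophil granule genes, the transcription factor gene Tbx1 and inducible heat shock genes. Ngp, a neutrophil granule protein, was highest among measured genes at 6.20-fold. S100a8 and S100a9, which form the neutrophil protein calprotectin, were above the floor on the null-labelled array only, at least 12.9-fold and at least 11.9-fold higher. The granule peptide Camp and the chitinase-like protein Chil3 were at least 4.84-fold and at least 3.30-fold higher. In a list of further neutrophil genes, added after these values were seen, 10 of the 15 above the floor on either array were higher. Of all genes above the floor on either array, 54.8% were higher. The 9 neutrophil genes of that list measured on both arrays had a median log2 ratio of 0.07, and 0 of them were at least 1.5-fold higher. A gene under the floor on 1 array, as S100a8 was, could not be among these 9. Hspa1b and Hspa1a, near-identical genes for the inducible chaperone HSP70 whose probe sets may share signal, were 3.76-fold and 3.26-fold higher. Heat shock proteins and chaperones together had a median of 0.36 over 22 genes, above every random list, and 20 of the 22 were above 0, among them Dnajb4 at 0.68 and Hsph1 at 0.58. Tbx1, a T-box transcription factor, was 4.19-fold higher, and Dmd, which encodes dystrophin, had 1.44 ± 0.59 (SD of 2 probe sets). Dusp26, a phosphatase, the Notch ligand Dll1 and the zinc finger gene Zfp385b were 3.40-fold, 2.66-fold and 2.65-fold higher.

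Markers of other cell types went in different directions. Erythroid genes had a median of 0.56 over 5 genes at percentile 99.96, led by Slc4a1, the anion exchanger of red cells, at 1.60 and Alas2, the first enzyme of heme synthesis in erythroid cells, at 0.70. That median is the value of Bpgm, and Fech had 0.54. On the wild-type-labelled array Bpgm and Fech read 1556 and 3056, while Slc4a1 and Alas2 read 310 and 212, nearer the floor. Schwann cell and nerve genes had a median of 0.34 over 11 genes at percentile 99.8. The myelin genes Ncmap, Mal and Pmp22 had 1.49, 0.88 and 0.65, while S100b, which brown fat also makes, had -2.46. General leukocyte markers had a median of -0.18 over 19 genes at percentile 0.94, with the macrophage receptor Cd163 at -0.68 and the immunoglobulin heavy chain Ighm at -0.84. Genes above the floor on 1 array only, S100a8 and S100a9 among them, enter no list median. MHC genes had a median of -0.49 over 8 genes at percentile 0.03, with H2-D1 at -0.73, and all 8 were below 0. Antioxidant genes had a median of -0.12 over 22 genes at percentile 0.24, with the metallothionein Mt1 at -1.63 and the glutathione peroxidase Gpx1 at -0.90. H2-Q10, of the MHC and hepatocyte lists, was above the floor on the wild-type-labelled array only. The MHC and antioxidant medians were not separated from the fat and liver genes lower on the same array, with an adipocyte median of -2.98 and 21 of 21 hepatocyte genes lower. Endothelial, smooth muscle, fibroblast and tendon lists lay within range, with medians of -0.02, 0.19, 0.10 and 0.05. The 3 measured skin genes had a median of 0.17. The Y-linked genes Eif2s3y, Kdm5d and Uty had 0.08, 0.35 and -0.04, and Eif2s3y turned sign in some of the alternatives.

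Lists of regulated programmes mostly lay within range. Immediate early genes had a median of -0.07 over 23 genes with Fos at 0.31, and circadian genes 0.03 over 17 genes with Dbp at 0.01 and Per1 at 0.03, both of which turned sign in some of the alternatives. Glucocorticoid, hypoxia and cell cycle lists had medians of 0.03, 0.18 and 0.15. The hypoxia list holds Kdm3a itself. Interferon response genes had a median of -0.01 and a mean of -0.44 over 15 genes, because 4 were at least 1.5-fold lower, among them Ifi27 at -3.78. Several medians within range, such as those of the glycolysis, circadian and cell cycle lists, changed sign under an alternative and are not read as a direction. In all, 14 of the 41 lists with 5 or more measured genes lay outside the central 95% of random lists, 10 below and 4 above. By construction 2.05 of 41 lists would if each were a random draw. The fixed lists share members, such as 12 of the 20 PPAR targets, and genes of 1 programme can vary together. The difference between these counts is therefore no measure of an excess.

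**Figure D2:**
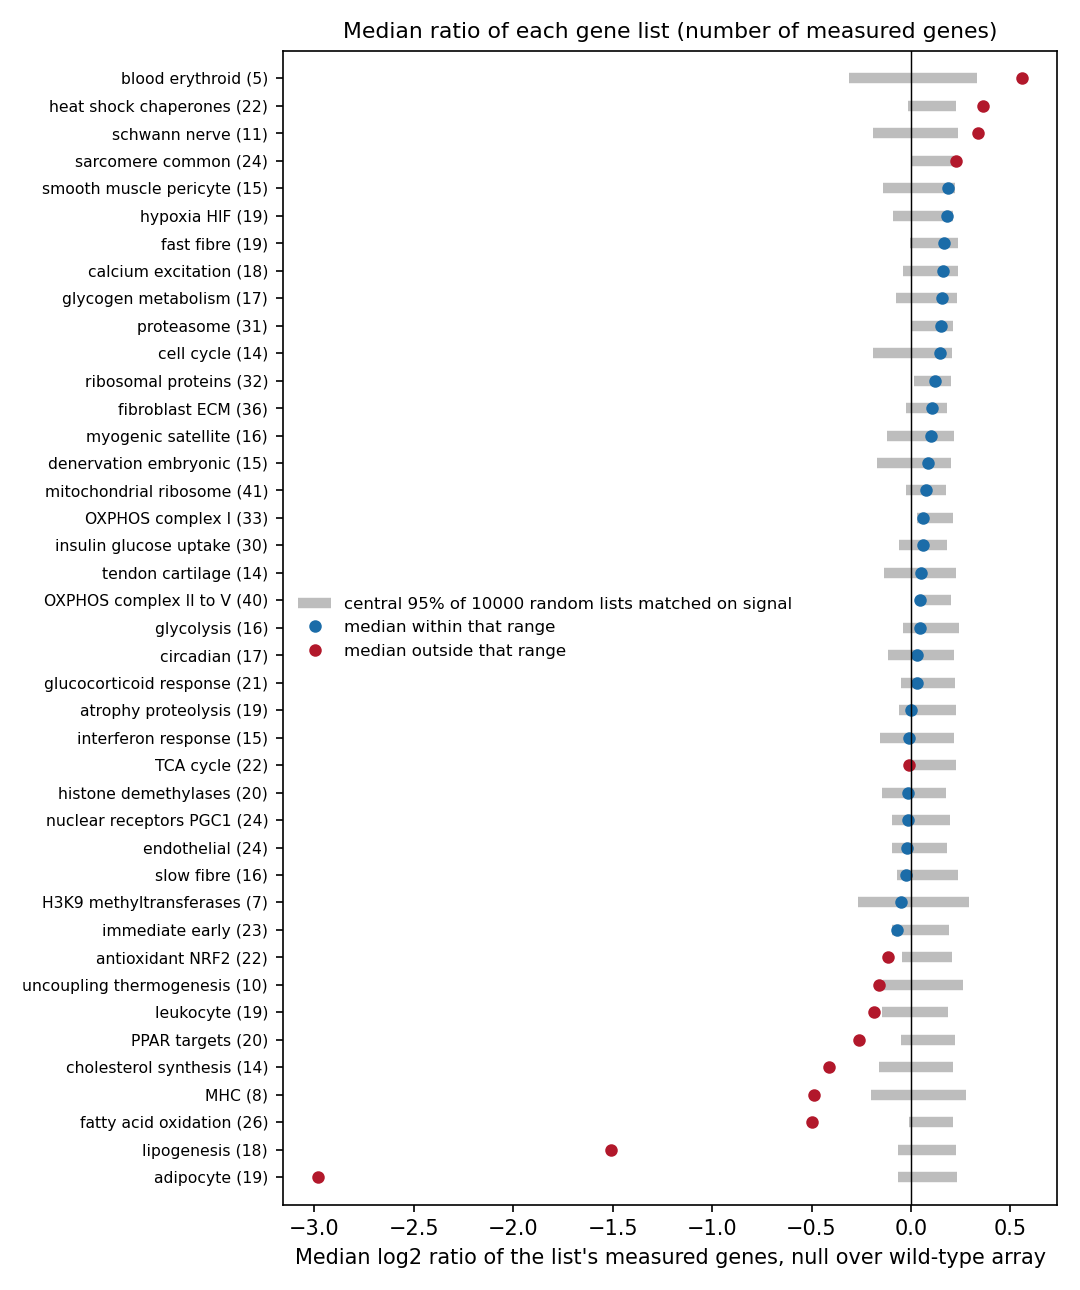
Median log2 ratio (x axis, null-labelled over wild-type-labelled array) of the measured genes in each of 41 gene lists (y axis, number of measured genes in brackets); points are list medians, grey bars the central 95% of 10000 random lists matched on signal. The adipocyte median lies at -2.98 and the erythroid median at 0.56; the small positive medians of the complex I and complex II to V lists turn negative after quantile normalization and loess.

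Genes near Kdm3a were examined because the strain label names 129 embryonic stem cells and linked 129 sequence can alter hybridisation. The 151 measured genes within 20 Mb of Kdm3a had a mean absolute log2 ratio of 0.275, at percentile 32.4 of 6320 windows of as many consecutive genes on other chromosomes. Of these genes, 5 differed by 2-fold or more. The largest differences were in the mitochondrial carrier Sfxn5 at -2.53, the folate enzyme Aldh1l1 at -1.78 and the monoglyceride lipase Mgll at -1.56.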

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

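Of 1466 measured probe sets without a single gene name, which entered no gene value or list, 7 were at least 2-fold higher and 39 at least 2-fold lower on the null-labelled array. They drew attention because they carry differences outside the gene-level comparison, and what they measure is unnamed here. The excess of lower over higher among them has the same direction as among named genes, where 36 were higher and 229 lower. No explanation was tested for them.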

How the results depend on the processing

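The removal of fat genes from the counts and from the PPAR targets, of Pcx and Idh3b from the tricarboxylic acid list, and the measured ratio or bound for unseen brown adipocyte genes (8 of 17 at least 2-fold lower, against 6) were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each genotype has 1 array. For the same reason no count could be repeated without a doubted array. The lower share of counted genes stayed between 84.8% and 91.1% over scaling, floor and probe set choices. The median of all genes was 0.0515 after quantile normalization and -0.0031 after loess. Loess and setting the median to 0 hold it near 0 by construction. Of 50 named genes past 2-fold, which lie far from a change of sign, 49 kept their sign in every alternative run. The exception was Idh3b, at 0.15 with the floor at the 75th percentile and 0.17 from its brightest probe set. Without members of the fat lists the counts were 36 higher and 207 lower. That removal leaves in Pygl, Prkar2b, Apoc1 and Tkt, which are among the 10 lowest genes. The 207 are therefore not genes shown to be free of a fat or liver contribution. Outside the range as reported and in every alternative that gave a value lay 11 lists, which include adipocyte, lipogenesis, fatty acid oxidation, PPAR targets and heat shock; the erythroid list gave no value in 2 alternatives. With random lists not matched on signal 12 lists lay outside instead of 14, among them all 11, while the thermogenic and tricarboxylic acid lists lay inside. The removal of fat genes took only Ucp3, Cd36, Lpl and Aqp7 from the PPAR targets and left the median at -0.26, so it says nothing about whether the median depends on fat. The nuclear receptor list lay outside in 1 of 8, the common sarcomere and thermogenic lists in 5 of 8, and the tricarboxylic acid list in 6 of 9. The values as deposited equal those of the main setting, so in all such counts that alternative could only repeat the main result.

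With the floor at the 75th percentile, 11 genes were higher and 113 lower, and at 1.5-fold 325 were higher and 608 lower; both follow from fewer genes measured or a wider threshold. For the following values the cause was not tested. Complex I had a median of -0.0100 after quantile normalization and -0.0384 after loess. Complexes II to V had -0.0330 after quantile normalization, 0.0023 with the median set to 0 and -0.0632 after loess, each outside the range of random lists. PPAR targets had -0.33 after quantile normalization, -0.37 after loess and -0.34 from the brightest probe set. The adipocyte median was -1.10 with the floor at the 75th percentile, -2.45 from the brightest probe set and -3.06 without _x_at and _s_at probe sets. Lipogenesis had -1.60 after loess, -1.05 and -0.92 with floors at the 50th and 75th percentiles, and -1.05 without _x_at and _s_at probe sets. Fatty acid oxidation had -0.60 after loess. Heat shock had 0.27 after loess and 0.29 from the brightest probe set. The fast-twitch list had 0.0549 after quantile normalization and 0.0546 after loess, and the slow-twitch list -0.11 after loess and 0.0933 from the brightest probe set.

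The tricarboxylic acid list turned sign to 0.0060 with the floor at the 75th percentile, 0.0014 from the brightest probe set, 0.0208 without _x_at and _s_at probe sets and 0.0060 without Pcx and Idh3b. The thermogenic list turned to 0.20 with the floor at the 75th percentile. Signal over the floor limits the dim genes, whose ratios are compressed or missing when 1 array falls under it.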

Other observations

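The lists of brown adipocyte, hepatocyte, neutrophil, bone and muscle enzyme genes used here, the muscle PPAR set and the isoform pairs were chosen after the 40 highest and lowest genes had been seen. The tests of unseen members were written before those members' own values had been looked at, except that of Hp in the neutrophil test. The medians of all fixed lists were known by then, among them the erythroid list and lists that hold some of the unseen members, such as S100b, Cox7a1, Lyz2 and Tyrobp.

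Transcripts of hepatocytes were also lower on the null-labelled array. All 21 hepatocyte genes above the floor on either array were lower, 16 of them at least 2-fold, with a median of 3.76-fold when signals under the floor are set to it. Ttr, the thyroid hormone carrier transthyretin, was at least 20.4-fold lower, the MHC gene H2-Q10, made mainly by liver, at least 14.9-fold lower, and the cytochrome Cyp2c29 at least 12.6-fold lower. Alb, serum albumin, read 2635 and 361, and Rbp4, the retinol carrier that fat also makes, had -2.60. Values of 6 of these genes (Alb, Ttr, Serpina1b, Serpina1c, Cyp2c29 and H2-Q10) had been seen before the list was written. Ppp1r3b, a glycogen-targeting phosphatase subunit of liver, was at least 17.3-fold lower, and Otop1, a proton channel of brown fat, at least 14.8-fold lower. Among 6 bone genes the osteoclast phosphatase Acp5 had -2.04 and the protease Ctsk 0.63.

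Some pairs of enzyme isoforms, picked after their values were seen, parted between the muscle form and its counterpart, and others did not. The muscle forms Pygm, Pfkm and Pgam2 had log2 ratios of 0.17, 0.17 and 0.21, and their counterparts in other tissues, Pygl, Pfkl and Pgam1, had -4.81, -3.31 and -2.50. The muscle subunits Cox6a2 and Cox8b of cytochrome oxidase had 0.27 and -0.13, and the widely expressed Cox6a1 and Cox8a had -2.04 and -1.64. The adenine nucleotide carriers Slc25a4 and Slc25a5 had 0.27 and -0.90. No such split was seen in Cox7a1 and Cox7a2 (0.03 and 0.04), Phkg1 and Phkg2 (0.15 and 0.13) or Slc2a4 and Slc2a1 (0.24 and 0.29). Over 17 muscle forms of metabolic enzymes 16 were above 0, with a median of 0.17 and a range from -0.13 to 0.35; after loess 13 were above 0 and the median was 0.0649. The 12 genes of the pairs that parted kept their signs under each scaling.

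Adipocyte, lipogenic and fatty acid oxidation genes were lower together in the null-labelled pool. One hypothesis is that the wild-type-labelled pool may have held brown adipose tissue: of 17 brown adipocyte genes whose values had not been seen, 6 (35.3%) were at least 2-fold lower, between the 25% under which it would have been set aside and the 50% asked for, while the muscle enzyme median was 0.17. The 6 were S100b, Orm1, Mrap, Pank1, Cpn2 and Acot11, and whether liver transcripts contribute to any of them was not tested. Among the other genes Zic1 had -0.34 and Aldh1a1 0.73. The 17 include Cox7a1, a muscle form in the pairs above that read 13555 and 13825, so muscle signal could mask a fall in it. The count of 6 averages the probe sets of a gene with signals under the floor set to it. With the measured ratio or bound of each gene, a rule added after seeing the data, it was 8 of 17 (47.1%), or 50% of the 16 genes with such a value, so the outcome lies near the bar and hangs on the rule. Another is lower PPAR-dependent expression inside the fibres: Ucp3, Pdk4, Fabp3 and Angptl4 had a median of 0.0701 where -0.50 was asked for, but they ranged from -2.49 to 0.46, and their median was -0.0195 after loess, so they decide nothing. Setting it aside asked for each of the 4 above a bar that Angptl4, at -2.49, fell under. For the fatty acid oxidation genes the 2 hypotheses cannot be told apart here, because each genotype is 1 pool and fat itself expresses PPAR targets. The fibre hypothesis concerns genes that fibres express. All 19 measured adipocyte markers were lower, with a median of -2.98, which argues against it as the only source of their difference. The hepatocyte transcripts lower with these markers (21 of 21 genes, Ttr at least 20.4-fold, Alb at -2.87) were not set against either hypothesis. Liver expresses fatty acid oxidation genes and Ppara too, and how much of their difference goes with it was not tested. A genotype effect on the amount or state of fat cells within muscle stays open and untested.

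Some neutrophil granule genes were higher in the null-labelled pool, S100a8 by at least 12.9-fold. Marrow or blood cells in that pool are a candidate source: of 15 further neutrophil genes 10 (66.7%) were higher, short of the 75% asked for and above the 50% that would have set it aside. Without Hp, a fat and liver product already known to be lower, it was 10 of 14 (71.4%). That count takes any ratio above 0, which 54.8% of all 10699 genes above the floor on either array had. Signals under the floor were set to it, so genes such as Ltf, which read 82.6 and 351.1, give only lower bounds on size. The 9 of these 15 genes measured on both arrays had a median log2 ratio of 0.07, with 5 above 0 and 4 below. Of those 9, 0 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. A gene under the floor on 1 array, as S100a8 was, could not be among the 9, so they cannot show whether such genes differ. The erythroid median of 0.56, the value of Bpgm, over 5 of 18 listed genes and without Hba-a1 or Hbb-b1, has the same direction as the granule genes. The general leukocyte median of -0.18 has the opposite, but S100a8 and S100a9, above the floor on 1 array only, enter no median. With 1 pool per genotype, marrow or blood cells in the pool cannot be told apart from a genotype effect on neutrophil number, which was not tested.

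Linked 129 sequence may alter hybridisation near Kdm3a, yet genes within 20 Mb differed no more than genes elsewhere, at percentile 32.4 (mean absolute log2 ratio 0.275, median of windows 0.289). Windows of 10 and 40 Mb gave percentiles of 51.6 and 35.3. A rule written beforehand would have set linked sequence aside if the 20 Mb value fell under the median of windows, and it did. The margin was less than the SD of the windows, 0.0282, which was not part of that rule, so a small effect of linked sequence stays open. Mgll, among the largest differences there, is also a lipase of fat.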
